A study of Salmo salar with 58 samples.

How the data were processed

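RNA was extracted with QIAzol and the EZ1 RNA Tissue Mini Kit, messenger RNA was enriched on oligo(dT) beads, and 150 bp paired reads were made on an Illumina NovaSeq instrument, per the labels' protocols. Reads were trimmed with Trim Galore 0.4.2 and inspected with FastQC, aligned with HISAT2 and counted per gene with featureCounts of Subread, and DESeq2 1.18.1 was used, per the submitters' processing notes. The version of HISAT2 and the genome build are not given in the sources used here, so no coordinates are printed. The deposited signal is a normalized count, in which each library's reads per gene are divided by a factor of that library, common to both tissues.

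That factor was worked out from the values: 99.9999% of them lie within 0.1 read of a whole read once multiplied back, and the largest distance is 0.17. The file holds 26239 genes by NCBI GeneID, and the lowest mean value over libraries is 21.1, so weakly expressed genes are absent. Names come from the reference assembly Ssal_v3.1, used for names alone: 24184 GeneIDs matched, 7529 of them with a symbol other than a LOC number. GeneIDs of the main genes are 100194475 (hoxa11ab), 100380390 (herpud1), 100195206 (epor), 100195152 (tal1), 106612265 (tsc22d3), 100195422 (tisb), 106565041 (ripor3), 100380459 (tmem43), 100194911 (5ntc) and 106604951 (rell2). Salmon carry many near-identical gene copies, and values of copies that share reads are uncertain.

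Because the values are normalized, the test differs from the one planned on counts with edgeR. Limma with a mean-variance trend and robust moderation was fitted to log2 of value plus 2, for genes with a value of 10 or more in at least 5 libraries of the tissue, with all 29 libraries of a tissue in the fit and Benjamini-Hochberg adjustment at 0.05. That left 25601 genes in intestine and 25157 in liver, and 24519 for the fit over both tissues. edgeR quasi-likelihood, DESeq2 and voom were run on the recovered reads. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0 and statmod 1.5.0.

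Of 33 gene lists fixed before the data were examined, those with 4 or more measured members were tested, 30 in intestine and 29 in liver. Members were matched by symbol alone, and the planned match by product name was not made. Genes with only a LOC number could therefore not be members. Camera with a preset correlation of 0.01 is the printed test; camera with an estimated correlation and fry stand beside it. Exact permutation tests of the mean over a list were added after the list results had been seen, and they are adjusted over the lists of a tissue. Genes named against control are the 8 rising and 8 falling with the smallest p among those past 0.05 that have a name, and for other contrasts 4 and 4; where none passes, the 3 with the smallest p. Members of a list are named as examples, up to 4 where they pass.

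On simulated counts with 200 changed genes, limma recovered 13.4, 47.8 and 87.9% of changes of 1.5, 2 and 4 times in intestine and 11.9, 61.2 and 93.9% in liver. False calls were 2.9 and 7.3% of those limma made, 2.9 and 5% for edgeR and 17 and 14% for DESeq2. Apart from the planted changes, genes were drawn independently around a mean common to all libraries. The simulation thus held no divergent library and no correlation between genes. These rates do not carry over to intestine comparisons with the divergent controls described below. No pair of libraries within a group was identical (lowest chi-square per degree of freedom 28.8).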

Results

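Polyadenylated RNA from the liver and the distal intestine of Atlantic salmon (Salmo salar) was sequenced 12 h after acute in vivo exposure to enniatin B or beauvericin, toxins made by Fusarium moulds of cereals. Both are cyclic hexadepsipeptides in which D-2-hydroxyisovaleric acid alternates with an N-methylated amino acid, which is N-methyl-L-valine in enniatin B and N-methyl-L-phenylalanine in beauvericin. The 58 libraries form 10 groups. In each tissue there were 6 controls, 6 samples of low enniatin B, 6 of high enniatin B, 5 of low beauvericin and 6 of high beauvericin. The labels name the doses only as low and high, so equal doses of both toxins are not assumed. They also do not say that each number is a different fish, so p-values of single genes and of exact permutations measure the spread between samples. Camera with a preset correlation compares the genes of a list with the other genes. Its p-value rests on that assumed correlation and is not a measure of the spread between samples. Depth was 23.3 to 40.6 M assigned reads per intestine library and 30.7 to 61.7 M per liver library. Controls held 23.3 to 39.3 M in intestine and 31.3 to 35.5 M in liver. High beauvericin was the deepest liver group at 35.3 to 61.7 M, with 57.8 and 61.7 M in replicates 1 and 3. No liver library of another group exceeded 39.9 M. Values are normalized read counts for 26239 genes, and fold changes are log2 values ± standard error.

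The intestine libraries differed among themselves before any treatment was considered. Controls 5 and 6 lacked the transcripts of absorbing enterocytes. npc1l1, the cholesterol uptake protein of the brush border, had normalized counts of 1.4 and 1.8 in them and 3720 or more in every other intestine library. apoa1, the main protein of HDL, had 34.3 and 25.2, against 214000 to 402000 in controls 1 to 4, and slc6a19, a neutral amino acid transporter, had 0 in both. cdx1b, a transcription factor of intestinal identity, had 0 and 19.8, against 3400 to 5030 in controls 1 to 4. The smooth muscle actin gene acta2 stood at 190000 and 224000, against 25000 to 112000 in the other 27 libraries. Their median correlations with the other intestine libraries were 0.589 and 0.601. Replicate 3 of low enniatin B had the next lowest correlation, 0.857, and there the endocytic receptor cubn stood at 47500 and the peptide transporter slc15a1 at 9.71. Every intestine comparison against control contains controls 5 and 6, so values without them stand beside the groups of genes concerned. Those values rest on controls 1 to 4, which may differ from the treated libraries in the position of sampling, as described below.

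**Figure D1:**
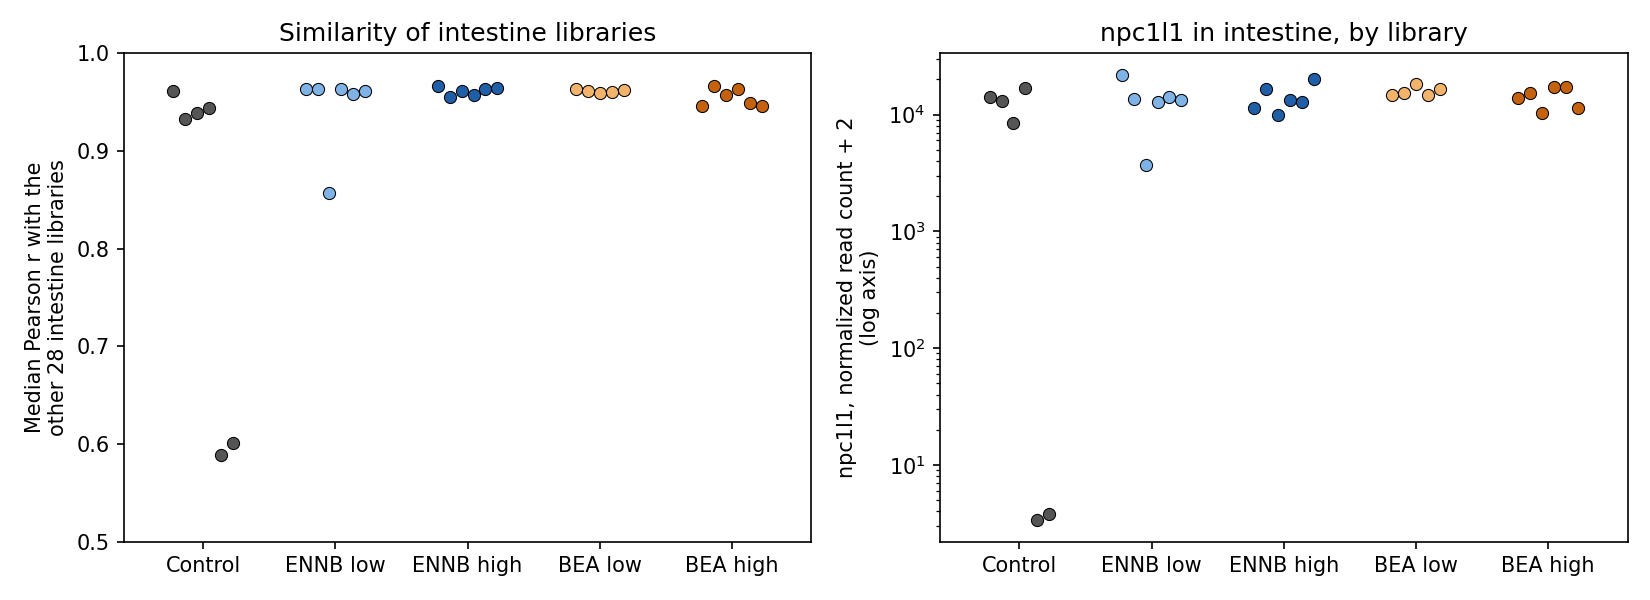
Left, the median Pearson correlation across genes of each intestine library with the other 28; right, the normalized read count of npc1l1 plus 2 on a log axis; each point is a library of the group named on the x axis. Controls 5 and 6 lie at 0.589 and 0.601, and replicate 3 of low enniatin B at 0.857.

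After low enniatin B, no intestinal gene passed the test, while genes of the absorptive cell lay higher as groups. All 10 measured members of the brush border and transporter list were higher than in control, with a median log2 change of 2.39, and all 9 members of the lipid absorption and bile acid transport list, with a median of 2.78. Among them were slc6a19 (4.54 ± 1.53), the sodium-glucose cotransporter slc5a1 (3.30 ± 1.37) and the sterol exporters abcg5 (3.29 ± 1.22) and abcg8 (3.66 ± 1.40). None of these members passed over all genes, and 6 and 5 passed when adjusted over the list alone. Both lists passed camera with a preset correlation (adjusted p = 9e-04 for each) and not with an estimated one (adjusted p = 0.77 with an estimated correlation for each). Their medians without controls 5 and 6 were 0.14 and 0.01, and the camera adjusted p-values 0.54 and 0.82. Replicate 3 of low enniatin B is itself low in some absorptive transcripts, such as slc15a1 at 9.71, but not in others, with cdx1b at 3910 and cubn at 47500. Without it as well the brush border list had a median of 0.17 (camera adjusted p = 0.051). The lipid absorption list had a median of 0.41 and passed (camera adjusted p = 0.024, adjusted p = 0.37 with an estimated correlation). The 7 measured red cell genes were all lower (median -0.47, camera adjusted p = 0.041, adjusted p = 0.77 with an estimated correlation), and without controls 5 and 6 the mean change went from -0.51 to -0.27 (camera adjusted p = 0.10). Without replicate 3 of low enniatin B as well, it was -0.37 and the list passed (camera adjusted p = 0.025, adjusted p = 0.37 with an estimated correlation).

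Among named genes the smallest p-values after low enniatin B belonged to hoxa11ab, slc35a2 and herpud1, each at a limma adjusted p of 0.20. The homeobox gene of the posterior body, hoxa11ab, had 2.42 ± 0.49 (n = 6 against 6), and 1.79 ± 0.46 without controls 5 and 6 (limma adjusted p = 0.52). The Golgi UDP-galactose transporter slc35a2 had -0.75 ± 0.15, and herpud1, an endoplasmic reticulum protein of misfolded-protein disposal, -0.58 ± 0.12. Herpud1 passed when adjusted over the list alone (adjusted p = 0.00079, limma). Of 25601 genes, 4472 had an unadjusted p under 0.05 and 0 passed in limma. The count in edgeR was 545 (62 higher, 483 lower) and in DESeq2 1582 (198 higher, 1384 lower). With controls 5 and 6 left out the counts were 0 in limma, 0 in edgeR and 9 in DESeq2. The limma count was 608 without control 4, most of them higher (412 higher, 196 lower), 2 without control 1 and 1 without replicate 3 of low enniatin B.

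High enniatin B gave the same 2 lists in intestine. Brush border genes had a median of 3.20, with 9 of 10 higher (camera adjusted p = 0.0013). Lipid absorption genes had a median of 2.94, with 9 of 9 higher (camera adjusted p = 0.00047). In each list 6 members passed when adjusted over the list alone and 0 over all genes. Both calls were lost at adjusted p = 0.56 with an estimated correlation. Leaving out controls 5 and 6 gave medians of 0.14 and 0.17 with camera adjusted p-values of 0.29 and 0.62. The cholesterol-esterifying enzyme soat2 was at 2.94 ± 1.12 and the triglyceride-forming enzyme dgat1a at 1.58 ± 0.47. The unfolded protein and amino acid response list was lower in 14 of 15 members (median -0.27, camera adjusted p = 0.0091, adjusted p = 0.65 with an estimated correlation). Its member herpud1 stood at 446 ± 49 normalized counts against 674 ± 117 in control (SD, n = 6 each; -0.58 ± 0.12), which passed only when adjusted over the list alone (limma adjusted p = 0.00076, and 0.20 over all genes). That list was lower without controls 5 and 6 as well (median -0.44, camera adjusted p = 3.7e-06, adjusted p = 0.32 with an estimated correlation). The 4 T and B cell markers were higher (median 0.68, camera adjusted p = 0.026, adjusted p = 0.56 with an estimated correlation), with cd8a at 1.17 ± 0.42, but their median without controls 5 and 6 was 0 (camera adjusted p = 0.98).

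No single gene passed limma after high enniatin B (4529 with an unadjusted p under 0.05), against 542 in edgeR (33 higher, 509 lower) and 1444 in DESeq2 (120 higher, 1324 lower). The smallest p-values among named genes were those of herpud1, wdr47a (0.80 ± 0.17) and hoxa11ab (2.28 ± 0.49), all at a limma adjusted p of 0.20. hoxa11ab had 1.64 ± 0.46 without controls 5 and 6 (limma adjusted p = 0.52). The counts without controls 5 and 6 were 0, 0 and 10. Without control 4 limma counted 1518, most of them higher (1037 higher, 481 lower), and without replicate 4 of high beauvericin 1.

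In the intestine hoxa11ab was higher after low beauvericin than in control. It stood at 134 ± 51 normalized counts (SD, n = 5) against 14.6 ± 10.1 in control (n = 6), and all 5 libraries lay above the control median. The log2 change was 3.25 ± 0.51 with a 95% interval of 2.20 to 4.30 (limma adjusted p = 0.022). The call was lost in voom (2.75, adjusted p = 0.32), in limma on these 2 groups alone (adjusted p = 0.63) and in limma without controls 5 and 6 (adjusted p = 0.097). The other 3 genes past the threshold have no name in the reference and were not picked by the rule for named genes: LOC106608992 (3.26 ± 0.55), LOC106588851 (3.14 ± 0.54) and LOC106572400 (0.95 ± 0.16), each at a limma adjusted p of 0.025. The other posterior members of the family did not pass, hoxa10ab at 2.71 ± 0.74 (limma adjusted p = 0.16), hoxc10aa at 1.39 ± 0.36 (0.15) and hoxc10ab at 0.32 (0.63). Nor did the middle members hoxa7aa (2.52, limma adjusted p = 0.14) and hoxc6ba (1.74, 0.21). Brush border genes (median 3.04, 9 of 10 higher) and lipid absorption genes (median 3.07, 9 of 9 higher) both passed camera at an adjusted p of 0.0016 and were lost at adjusted p = 0.80 with an estimated correlation. In each list 6 members passed when adjusted over the list alone and 0 over all genes, and without controls 5 and 6 the medians were 0.25 and 0.30 (camera adjusted p = 0.13 and 0.33).

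Red cell genes were lower in 6 of 7 members after low beauvericin (median -0.63, camera adjusted p = 0.02, adjusted p = 0.80 with an estimated correlation). The blood-forming transcription factors tal1 (-0.91 ± 0.34) and nfe2 (-0.43 ± 0.15) passed when adjusted over the list alone. Oxidative phosphorylation genes were lower in 31 of 46 (median -0.13, camera adjusted p = 0.02, adjusted p = 0.87 with an estimated correlation), and T and B cell markers higher (median 0.66, camera adjusted p = 0.033, adjusted p = 0.80 with an estimated correlation). Without controls 5 and 6 the mean change of the red cell list went from -0.57 to -0.33 (camera adjusted p = 0.056), and the T and B cell list had a median of -0.01. Oxidative phosphorylation genes were then lower in 41 of 46 (camera adjusted p = 3.1e-10, adjusted p = 0.56 with an estimated correlation).

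For low beauvericin limma counted 4 higher and 0 lower (4783 with an unadjusted p under 0.05), edgeR 40 and 291, DESeq2 209 and 1425, and limma on these 2 groups alone 0. Without controls 5 and 6 the counts were 1 in limma, 1 in edgeR and 37 in DESeq2. The limma gene was LOC106572400 (1.09 ± 0.16, adjusted p = 0.0053), and hoxa11ab had 2.62 ± 0.48 (limma adjusted p = 0.097). The limma count was 0 without replicate 2 or 4 of low beauvericin, 1 without its replicate 3 or control 3 or 5, 2 without its replicate 1 or control 2 or 6. It was 9 without replicate 3 of low enniatin B, 100 without control 1 (81 higher, 19 lower) and 1067 without control 4 (765 higher, 302 lower).

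The same gene, hoxa11ab, was also the 1 intestinal gene past the threshold after high beauvericin, at 113 ± 46.7 normalized counts (SD, n = 6) against 14.6 ± 10.1 in control (n = 6). Its log2 change was 2.99 ± 0.49 with a 95% interval of 1.99 to 3.99, and 6 of 6 libraries lay above the control median (limma adjusted p = 0.039). Here too the call was lost in voom (2.49, adjusted p = 0.81) and in limma on these 2 groups alone (adjusted p = 0.69). Brush border genes (median 2.76, 10 of 10 higher) and lipid absorption genes (median 2.63, 9 of 9 higher) passed camera at an adjusted p of 0.00079 each, calls lost at adjusted p = 0.86 with an estimated correlation. In each list 6 members passed when adjusted over the list alone and 0 over all genes. The actin-bundling protein vil1 was at 1.78 ± 0.76 and npc1l1 at 4.06 ± 1.57. Cell cycle genes were higher in 17 of 18 (median 0.40, camera adjusted p = 0.024, adjusted p = 0.88 with an estimated correlation), with the replication licensing genes mcm5 at 1.32 ± 0.61 and mcm3 at 1.03 ± 0.52. Both absorption medians were 0.02 without controls 5 and 6 (camera adjusted p = 0.52 and 0.88). The lists that then passed were oxidative phosphorylation (42 of 46 lower, camera adjusted p = 5.2e-07) and proteasome (17 of 17 lower, camera adjusted p = 0.014), each at adjusted p = 0.68 with an estimated correlation.

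For high beauvericin 4322 genes had an unadjusted p under 0.05. In edgeR the counts were 24 higher and 463 lower, in DESeq2 112 and 1225, and in limma on these 2 groups alone 0. Without controls 5 and 6 the counts were 1 in limma, 0 in edgeR and 6 in DESeq2. The limma gene was LOC106570446 (2.19 ± 0.35, adjusted p = 0.03), and hoxa11ab had 2.36 ± 0.46 (limma adjusted p = 0.23). It passed again without replicate 3 of low enniatin B as well (2.36 ± 0.40, limma adjusted p = 0.047). On the same libraries hoxa11ab missed in edgeR (2.53, adjusted p = 0.07) and passed in DESeq2 (2.53, adjusted p = 7.1e-06). The limma count was 23 without control 4 (20 higher, 3 lower) and 1 without control 1, replicate 3, 5 or 6 of low enniatin B, 2 or 4 of high enniatin B, 1 of low beauvericin or 3 of high beauvericin. It was 0 without any of the other 20 libraries.

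**Figure D2:**
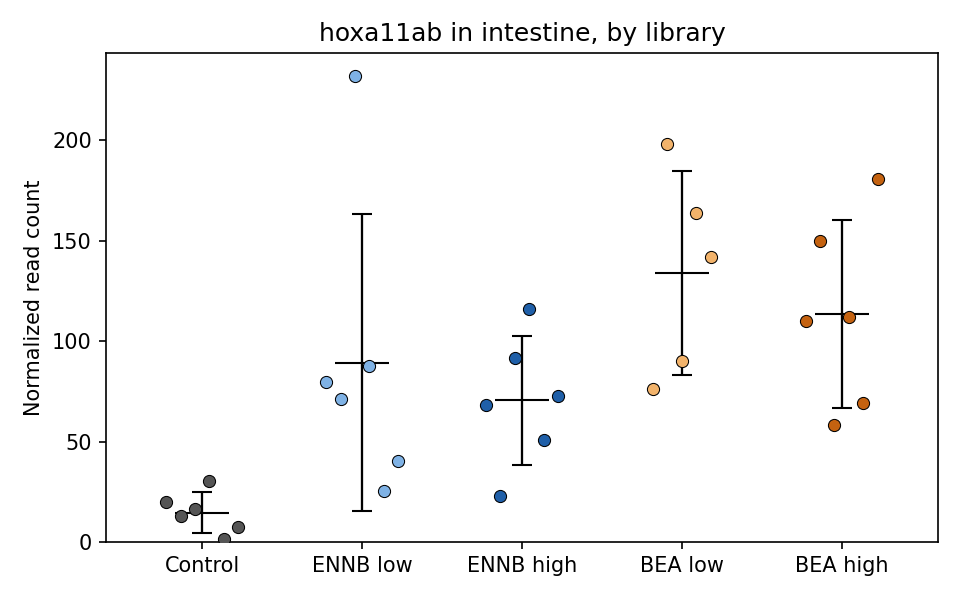
Normalized read count of hoxa11ab in each intestine library by group; points are libraries, the horizontal line is the mean and the bars the SD. Controls lie between 1.4 and 30.1, low beauvericin between 76.2 and 198 and high beauvericin between 58 and 181.

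Set directly against each other at the low dose, the toxins stood apart in intestine in a glucocorticoid-responsive list, in camera but not in every test. All 8 members were lower after enniatin B than after beauvericin, with a median log2 difference of -0.61 (camera adjusted p = 8.8e-06, adjusted p = 0.024 with an estimated correlation). The largest were tsc22d3, the glucocorticoid-induced leucine zipper (-0.98 ± 0.30; 2070 ± 776 against 3950 ± 824 normalized counts, SD, n = 6 and 5), and the transcription factors cebpb (-0.82 ± 0.25) and cebpd (-0.65 ± 0.24). These 3 passed when adjusted over the list alone and 0 over all genes. The mean over the list differed by -0.51 with a 95% interval of -0.84 to -0.18 (exact two-sided permutation p = 0.0043, adjusted p = 0.13 over 30 lists). Fry, which asks whether the members move one way, gave an adjusted p of 0.15. With controls 5 and 6 left out, the call was lost at adjusted p = 0.14 with an estimated correlation (camera adjusted p = 8e-05). Without replicate 3 of low enniatin B as well, 7 of 8 members were lower (median -0.51, camera adjusted p = 2e-05, adjusted p = 0.078 with an estimated correlation). Cell cycle genes were higher after enniatin B in 18 of 18 (median 0.34, camera adjusted p = 1e-05, adjusted p = 0.69 with an estimated correlation). Oxidative phosphorylation genes were higher in 38 of 46 (median 0.07, camera adjusted p = 0.0016, adjusted p = 0.76 with an estimated correlation).

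At the high dose 16 of 18 cell cycle members were lower after enniatin B (median -0.35, camera adjusted p = 0.0015, adjusted p = 0.86 with an estimated correlation). Unfolded protein response genes were lower in 14 of 15 (median -0.35, camera adjusted p = 2.8e-05, adjusted p = 0.73 with an estimated correlation), with the secreted stress protein manf at -1.11 ± 0.55. Proteasome genes were lower in 15 of 17 (median -0.14, camera adjusted p = 0.015, adjusted p = 0.86 with an estimated correlation). Inflammatory and acute phase genes were higher in 6 of 6 (median 0.41, camera adjusted p = 0.025, adjusted p = 0.18 with an estimated correlation), among them the matrix proteases mmp9 (0.80 ± 0.44) and mmp13 (0.62 ± 0.46).

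By single genes, limma found 0 differences between the toxins at the low dose in intestine (391 with an unadjusted p under 0.05; edgeR 0, DESeq2 2) and 0 higher and 1 lower at the high dose (778; edgeR 1, DESeq2 6). That 1 was LOC106609634, named here outside the rule for named genes (-0.65 ± 0.10, limma adjusted p = 0.011). It was lost in limma on these 2 groups alone and without replicate 2, 4 or 5 of high beauvericin or 1 of high enniatin B, with a count of 0 in each. The smallest p-values among named genes at the low dose were those of rigi, a sensor of viral RNA (-0.33 ± 0.10), myc (-0.58 ± 0.17) and tsc22d3, each at a limma adjusted p of 1. A missed threshold does not show that the toxins act alike. The 95% interval of the difference lay within 1 log2 unit either way for 20761 of 25601 genes (81.1%) at the low dose and 20892 (81.6%) at the high dose, with a median distance from estimate to limit of 0.45 and 0.43.

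Between doses of the same toxin, cell cycle genes of the intestine passed camera for both toxins, but not with an estimated correlation. They were lower at the high than at the low dose of enniatin B in 17 of 18 (median -0.31, camera adjusted p = 0.0055, adjusted p = 0.82 with an estimated correlation). They were higher at the high dose of beauvericin in 18 of 18 (median 0.47, camera adjusted p = 4.1e-06, adjusted p = 0.72 with an estimated correlation). The difference between these directions was not tested. The mean of the cell cycle list in beauvericin was 7.79 ± 0.10 at the high and 7.33 ± 0.16 at the low dose (log2, SD, n = 6 and 5; exact two-sided permutation p = 0.0022, the smallest these samples can give, adjusted p = 0.065 over 30 lists). With the spread of all 29 intestine libraries the 95% interval of that difference was -0.29 to 1.21. Glucocorticoid-responsive genes were lower at the high dose of beauvericin in 7 of 8 (median -0.44, camera adjusted p = 0.0054, adjusted p = 0.44 with an estimated correlation). Limma found 0 genes for either toxin (444 and 467 with an unadjusted p under 0.05; edgeR 0 and 0, DESeq2 1 and 3). Named genes with the smallest p-values were setd4 (-0.64 ± 0.17), the kinase map2k2b (-0.52 ± 0.15) and the DNA repair gene abraxas1 (0.53 ± 0.17) for enniatin B at a limma adjusted p of 1. For beauvericin they were ankrd24 (-1.94 ± 0.39, limma adjusted p = 0.82), endouc (-0.61 ± 0.17) and the tetraspanin cd82 (-0.45 ± 0.14), the latter 2 at a limma adjusted p of 1.

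In the liver the red cell genes lay lower as a group after low enniatin B than in control. All liver comparisons against control share the same 6 controls, so their agreement on these genes is not independent. Whether the livers held less blood was not tested for enniatin B. All 7 measured members were lower than in control, with a median log2 change of -0.83. The erythropoietin receptor epor stood at 152 ± 43.4 against 315 ± 63.7 normalized counts (SD, n = 6 each; -1.07 ± 0.25). Next come the blood-forming transcription factors tal1 (118 ± 57.1 against 255 ± 51.2), gata1 (-0.83 ± 0.34) and nfe2 (-0.53 ± 0.20). The remaining members are the red cell carbonic anhydrase cahz (-0.93 ± 0.35), the membrane skeleton protein ank1a (-0.78 ± 0.24) and the Rhesus-associated glycoprotein rhag (-0.35 ± 0.24). All but rhag, 6 in number, passed when adjusted over the list alone and 0 over all genes. No globin gene is among the members, which were matched by symbol, so globin genes with only a LOC number were not looked for. The list passed camera at an adjusted p of 1.6e-12 and kept its call at adjusted p = 0.01 with an estimated correlation and at 0.011 by fry. Its mean fell by 0.81 on the log2 scale (95% interval -1.22 to -0.41) from 8.45 ± 0.23 to 7.63 ± 0.30, with 6 of 6 libraries under the control median. The exact two-sided permutation p was 0.0022, the smallest these samples can give, with an adjusted p of 0.063 over 29 lists. A list that reaches that p alone cannot pass this adjustment. Limma found 0 single genes (915 with an unadjusted p under 0.05; edgeR 0, DESeq2 5, and 1 with the replicate number as a block). The smallest p-values among named genes were those of tal1 and epor (limma adjusted p = 0.42) and tmem43, an inner nuclear membrane protein (-0.70 ± 0.17, limma adjusted p = 0.51).

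After high enniatin B red cell genes were lower in liver than in the same controls, 7 of 7 with a median of -0.57 (camera adjusted p = 1.4e-05), a call lost at adjusted p = 0.36 with an estimated correlation. Of these, epor passed when adjusted over the list alone (-0.89 ± 0.25) and 0 over all genes. Cholesterol synthesis genes were lower in 12 of 14 (median -0.50, camera adjusted p = 5.3e-08, adjusted p = 0.37 with an estimated correlation). Among them were hmgcs1 at -0.82 ± 0.46, idi1 at -0.79 ± 0.32 and fdft1, the first enzyme committed to sterols, at -0.76 ± 0.42. In this list 0 passed when adjusted over the list alone and 0 over all genes. Cell cycle genes were lower in 17 of 18 (median -0.35, camera adjusted p = 0.00072, adjusted p = 0.45 with an estimated correlation). Oxidative phosphorylation genes were lower in 34 of 46 (median -0.09, camera adjusted p = 0.00046, adjusted p = 0.48 with an estimated correlation). Coagulation genes were higher in 9 of 10 (median 0.09, camera adjusted p = 0.047, adjusted p = 0.45 with an estimated correlation). Limma found 0 single genes (696 with an unadjusted p under 0.05; edgeR 0, DESeq2 2, and 1 with the replicate number as a block). Named genes with the smallest p-values were the homeobox gene hxb7a (1.15 ± 0.30), epor and the mitochondrial thiolase acaa2 (0.60 ± 0.18), each at a limma adjusted p of 1. The limma count was 1 without replicate 6 of high enniatin B, 2 of low enniatin B, 5 of low beauvericin or 3 of high beauvericin.

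In the liver, 5 genes rose and 27 fell after low beauvericin in limma. The erythropoietin receptor gene epor fell by 1.30 ± 0.26 on the log2 scale, from 315 ± 63.7 to 127 ± 32.2 normalized counts (SD, n = 6 and 5; limma adjusted p = 0.035). The transcription factor tal1 fell by 1.39 ± 0.29, from 255 ± 51.2 to 101 ± 42.8 (limma adjusted p = 0.045). The glucocorticoid-induced leucine zipper tsc22d3 rose by 1.65 ± 0.34, from 2480 ± 1230 to 7310 ± 2030 (limma adjusted p = 0.045). The gene tisb, of the zinc finger family that destabilizes AU-rich messengers, rose from 5900 ± 2350 to 13100 ± 3820 (limma adjusted p = 0.037). The other named genes fell: ripor3 (-1.37 ± 0.25, limma adjusted p = 0.017), tmem43 (-0.93 ± 0.18, 0.022), the purine nucleotidase 5ntc (-1.57 ± 0.31, 0.028) and rell2 (-0.94 ± 0.19, 0.040). For each of these 8 genes all 5 libraries lay beyond the control median. The remaining 24 have no name in the reference. The 3 that rose were LOC106581841 (2.22 ± 0.39), LOC106592182 (1.54 ± 0.28) and LOC106601729 (1.04 ± 0.21). The smallest p was that of LOC106573055 (-1.46 ± 0.21, limma adjusted p = 0.0028). All 4 are named here outside the rule for named genes.

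Red cell genes fell as a group in liver after low beauvericin, 7 of 7 members with a median of -1.16 (camera adjusted p = 2.8e-11, adjusted p = 0.018 with an estimated correlation, fry adjusted p = 0.0016). 2 of them, epor and tal1, passed over all genes and 6 when adjusted over the list alone, including ank1a (-1.16 ± 0.25), gata1 (-1.27 ± 0.35) and cahz (-0.94 ± 0.37). The list mean fell by 1.01 (95% interval -1.44 to -0.58) to 7.44 ± 0.16, with 5 of 5 libraries under the control median (exact two-sided permutation p = 0.0022, the smallest these samples can give, adjusted p = 0.063 over 29 lists). The erythroid heme enzyme alas2, which is in another list, was at -1.17 ± 0.41. Glucocorticoid-responsive genes were higher in 7 of 9 (mean 0.67, median 0.13, camera adjusted p = 0.0072), a call lost at adjusted p = 0.25 with an estimated correlation. 1 of them passed over all genes and 3 when adjusted over the list alone: tsc22d3, cebpd (1.23 ± 0.31) and igfbp1a, a binding protein of insulin-like growth factors (3.15 ± 0.81). Immediate early genes were higher in 8 of 10 (median 0.67, camera adjusted p = 0.0056, adjusted p = 0.25 with an estimated correlation), with egr1 at 1.27 ± 0.60, ier2 at 1.05 ± 0.40 and myc at 0.77 ± 0.26. Cholesterol synthesis genes were lower in 13 of 14 (median -0.42, camera adjusted p = 0.00048, adjusted p = 0.55 with an estimated correlation), of which mvk (-0.76 ± 0.23) passed when adjusted over the list alone and 0 over all genes. Coagulation genes were higher in 9 of 10 (median 0.16, camera adjusted p = 0.028, adjusted p = 0.46 with an estimated correlation).

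Of 25157 liver genes 2080 had an unadjusted p under 0.05 after low beauvericin. In edgeR the counts were 4 higher and 17 lower, DESeq2 18 and 69. The limma count of 32 was 1 without control 1, 4 without replicate 2 of low beauvericin, 10 without control 6 or replicate 4 of low beauvericin, 13 without control 5, 14 without replicate 5 of low beauvericin and 21 without control 4. Of the 29 fits that left out a library, tsc22d3 passed in 12, tal1 in 11, epor in 20 and ripor3 in 26. Several named calls were lost in other fits. In voom the adjusted p was 0.072 for tsc22d3, 0.084 for tal1 and 0.061 for 5ntc. In edgeR it was 0.061 for tsc22d3, 0.096 for tal1 and 0.058 for rell2. In limma on these 2 groups alone it was 0.14 for tisb, 0.075 for tsc22d3 and 0.087 for rell2.

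**Figure D3:**
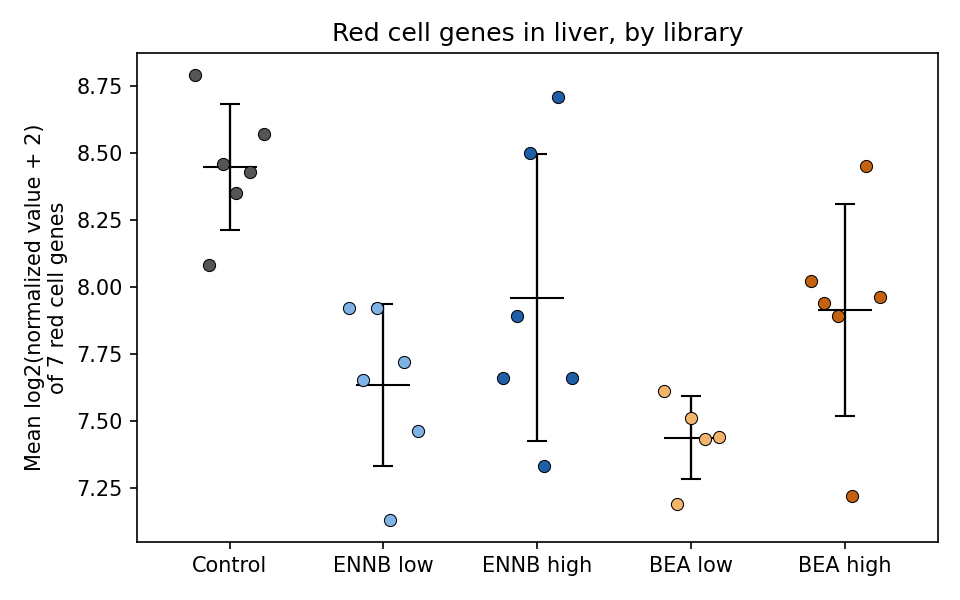
Mean log2 of normalized count plus 2 over the 7 measured red cell genes in each liver library, by group; points are libraries, the horizontal line is the mean and the bars the SD, and the axis does not start at 0. The control mean is 8.45 and those of low enniatin B and low beauvericin are 7.63 and 7.44.

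**Figure D4:**
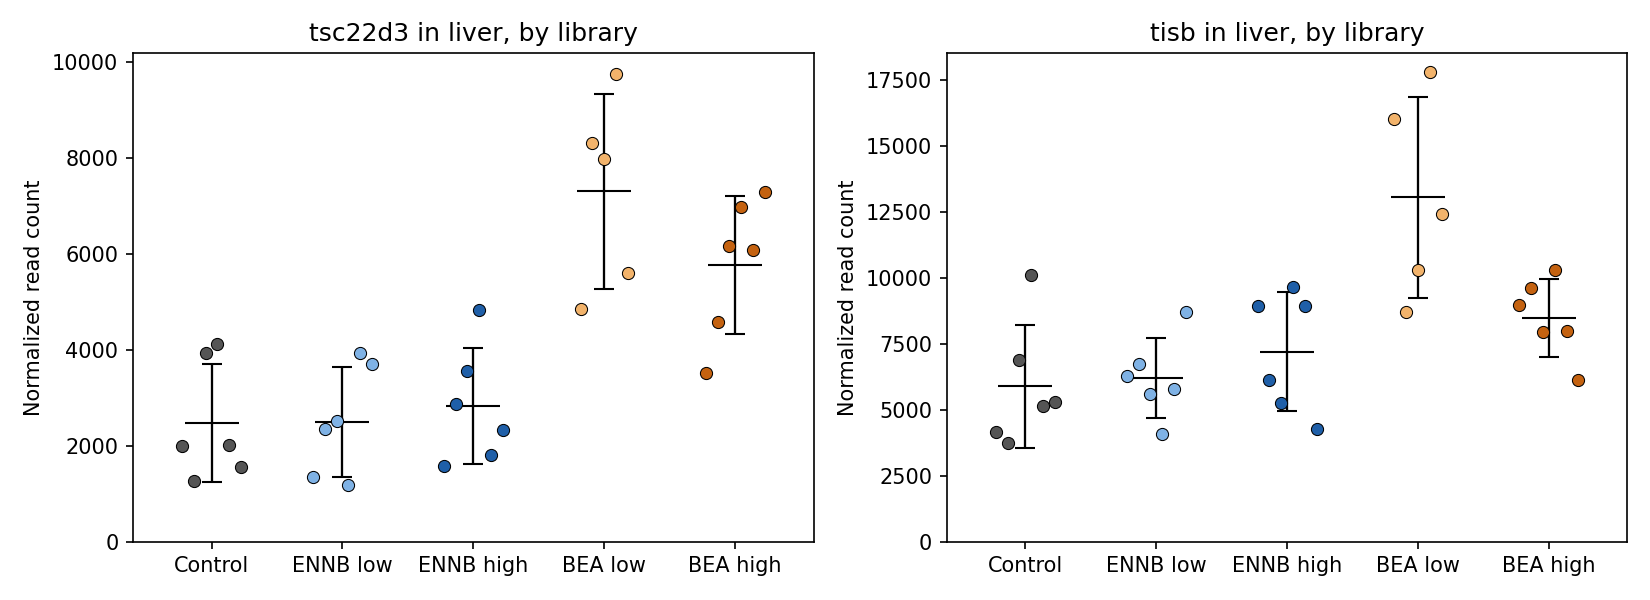
Normalized read counts of tsc22d3 (left) and tisb (right) in each liver library by group; points are libraries, the horizontal line is the mean and the bars the SD. tsc22d3 averages 2480 in control, 2510 after low enniatin B and 7310 after low beauvericin.

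After high beauvericin the liver red cell genes were all lower than in the same controls (7 of 7, median -0.62, camera adjusted p = 0.0012), a call lost at adjusted p = 0.93 with an estimated correlation. 3 members passed when adjusted over the list alone, epor (-0.87 ± 0.25), tal1 (-0.83 ± 0.28) and ank1a (-0.63 ± 0.24), and 0 over all genes. Fatty acid oxidation genes were higher in 13 of 14 (median 0.20, camera adjusted p = 0.0066) and oxidative phosphorylation genes in 36 of 46 (median 0.11, camera adjusted p = 0.005), both at adjusted p = 0.93 with an estimated correlation. tsc22d3 (1.32 ± 0.33) and cebpd (0.85 ± 0.29) passed when adjusted over the list alone, in a list that did not pass as a whole (camera adjusted p = 0.35). Limma found 0 single genes (2376 with an unadjusted p under 0.05; edgeR 0, DESeq2 36). This group was the most deeply sequenced in liver, with a mean of 44.2 M reads against 33.9 M in control. An effect of depth was not tested. The smallest p-values among named genes were those of the microtubule-severing katnal2 (-1.11 ± 0.23) and of the ribosomal protein genes rps26 (0.48 ± 0.10) and rs29 (0.76 ± 0.16), each at a limma adjusted p of 0.21.

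In liver, glucocorticoid-responsive genes lay lower after low enniatin B than after low beauvericin in camera, though not with an estimated correlation. In 8 of 9 members the value after enniatin B was below that after beauvericin (median -0.37, mean -0.79; camera adjusted p = 9.1e-05), with adjusted p = 0.077 with an estimated correlation. 3 members passed when adjusted over the list alone and 0 over all genes: tsc22d3 (-1.63 ± 0.34; 2510 ± 1150 against 7310 ± 2030 normalized counts, SD, n = 6 and 5), cebpd (-1.24 ± 0.31) and igfbp1a (-2.88 ± 0.81). The list mean differed by -0.79 with a 95% interval of -1.19 to -0.40, and 6 of 6 enniatin B libraries lay under the beauvericin median (exact two-sided permutation p = 0.0022, the smallest these samples can give, adjusted p = 0.063 over 29 lists). Immediate early genes were lower after enniatin B in 9 of 10 (median -0.53, camera adjusted p = 0.0067, adjusted p = 0.22 with an estimated correlation). The mean of the red cell list differed by 0.20 with an interval of -0.23 to 0.62 at the low dose and by 0.05 with an interval of -0.36 to 0.45 at the high dose.

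At the high dose, oxidative phosphorylation genes were lower after enniatin B than after beauvericin in liver, 40 of 46 with a median of -0.19 (camera adjusted p = 7.6e-09, adjusted p = 0.55 with an estimated correlation). 7 passed when adjusted over the list alone and 0 over all genes, for example ndufb3 (-0.62 ± 0.15) and ndufa2 (-0.44 ± 0.14) of complex I and uqcrc2b (-0.46 ± 0.13) of complex III. Heme synthesis genes were lower in 9 of 9 (median -0.26, camera adjusted p = 0.0035, adjusted p = 0.55 with an estimated correlation), of which cpox (-0.49 ± 0.14) and ppox (-0.34 ± 0.12) passed when adjusted over the list alone. Cholesterol synthesis genes were lower in 13 of 14 (median -0.48, camera adjusted p = 0.0012, adjusted p = 0.62 with an estimated correlation). Here too the high beauvericin libraries were the deeper, with a mean of 44.2 M reads against 33.6 M after high enniatin B.

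By single genes limma found 0 differences between the toxins in liver at either dose (1005 and 2587 with an unadjusted p under 0.05; edgeR 4 and 0, DESeq2 21 and 47, limma on the 2 low groups alone 2). At the low dose the smallest p-values among named genes were those of tsc22d3 and the connective tissue growth factor ctgf (-1.57 ± 0.34), both at a limma adjusted p of 0.20, and tisb (-1.06 ± 0.24, 0.27). At the high dose they were those of rs29 (-0.87 ± 0.16, limma adjusted p = 0.13), rps26 (-0.47 ± 0.10, 0.18) and the aldolase dera (-0.68 ± 0.15, 0.18). The 95% interval lay within 1 log2 unit either way for 20319 of 25157 genes (80.8%) at the low and 20105 (79.9%) at the high dose, with a median distance from estimate to limit of 0.44 and 0.42. Without replicate 3 of low beauvericin the count at the low dose was 2, and 1 without its replicate 2, control 3 or replicate 3 of low enniatin B. Without replicate 6 of high enniatin B the count at the high dose was 7, and 1 without replicate 3 of high beauvericin.

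Comparing doses in liver, beauvericin at the high dose left several lists nearer to control than at the low dose. Red cell genes were higher at the high than at the low dose in 7 of 7 (median 0.53, camera adjusted p = 2e-04, adjusted p = 0.35 with an estimated correlation). Cholesterol synthesis genes were higher in 14 of 14 (median 0.38, camera adjusted p = 2e-04, adjusted p = 0.42 with an estimated correlation). Immediate early genes were lower in 8 of 10 (median -0.47, camera adjusted p = 0.00026, adjusted p = 0.13 with an estimated correlation). For enniatin B, red cell genes were higher at the high dose in 7 of 7 (median 0.26, camera adjusted p = 0.01) and cholesterol synthesis genes lower in 13 of 14 (median -0.28, camera adjusted p = 0.013), both at adjusted p = 0.71 with an estimated correlation. Limma found 0 genes for either toxin (771 for enniatin B and 955 for beauvericin with an unadjusted p under 0.05; edgeR 0 and 1, DESeq2 2 and 8), and 1 for beauvericin without its low replicate 3. For enniatin B the smallest p-values among named genes were those of si:dkey-174n20.1 (-0.96 ± 0.25), the cardiolipin-remodelling gene tafazzin (0.99 ± 0.28) and sptlc1 of sphingolipid synthesis (-0.37 ± 0.10), each at a limma adjusted p of 1. For beauvericin they were pcy2 of phosphatidylethanolamine synthesis (-0.64 ± 0.16, limma adjusted p = 0.88), plcxd1.2 (0.80 ± 0.20) and the lysyl oxidase loxl3b (0.59 ± 0.15), the latter 2 at a limma adjusted p of 1.

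Whether liver and intestine responded differently to the high doses was tested as the difference of their log2 changes over all 58 libraries. The fit and its splits treat these libraries as independent. The labels do not say whether intestine and liver of the same treatment and number come from the same fish, but their correlations, given below, point to it. For enniatin B, ezrb, which encodes the microvillus linker ezrin, had 2.28 ± 0.58, elapor1 3.27 ± 0.82 and the annexin anxa14 -4.04 ± 1 (liver minus intestine), at limma adjusted p-values of 0.42 to 0.44. For beauvericin rps26 had 0.91 ± 0.18 (limma adjusted p = 0.10), rhbdd3 1.02 ± 0.22 and exoc3l2b -1.64 ± 0.37 (both 0.17). Of 24519 genes 0 passed in limma for either toxin (2311 and 2872 with an unadjusted p under 0.05). edgeR counted 304 (297 higher, 7 lower) and 405 (375 higher, 30 lower), DESeq2 559 and 750. With controls 5 and 6 of intestine left out, edgeR counted 1 and 2 and DESeq2 8 and 19. The limma count for enniatin B was 9 without control 4 and 1 without control 3 of intestine. For beauvericin it was 10 without control 4, 6 without control 1, 3 without control 2, 2 without liver control 1 and 1 without intestine replicate 3 of high beauvericin.

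Across genes, which are not independent replicates, the log2 changes after high enniatin B and high beauvericin correlated at 0.91 in intestine and 0.44 in liver. Both comparisons share their controls. Simulated unchanged groups were made by removing each group's mean and shuffling the libraries over the 3 groups. Their mean correlations were 0.44 (-0.84 to 0.94) in intestine and 0.49 (0.09 to 0.74) in liver. In these shuffles controls 5 and 6 could fall into a toxin group, whereas in the data both are controls. The simulated intestinal values therefore do not show what sharing these very controls gives, and a distance from them is no measure of a shared response. The covariance was 0.357 in intestine against a simulated mean of 0.0724 and a highest simulated value of 0.505, a difference of 0.285. In liver it was 0.0438 against 0.0492, a difference of -0.00534. With separate controls, 3 for each toxin, the mean correlation was 0.41 (-0.18 to 0.81) in intestine and -0.05 (-0.26 to 0.08) in liver. Without controls 5 and 6 the intestinal correlation was 0.62 against a simulated mean of 0.58, and the covariance 0.0546 against 0.0463, a difference of 0.00837. With separate controls as well, the mean correlation was -0.07 (-0.41 to 0.13).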

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

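Of the tests in this part, the thinning of reads and the comparison of sampling position were written down beforehand; the tests with liver genes, gut regions, remaining fold, size factors and white cell genes were chosen only after the result was seen.

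Controls 5 and 6 of intestine lack enterocyte transcripts, with npc1l1 at 1.4 and 1.8 normalized counts. Lower depth does not account for it: with every intestine library thinned to 23.3 M reads their median correlations were 0.587 and 0.599, and the lowest of the other 27 was 0.856. Liver RNA does not either, since 20 abundant liver genes had medians of 0.000508 and 0.00116% of the liver level in them. These genes were chosen for being low in the other 27 intestine libraries. Tissue from another part of the gut remains possible: over 4 intestinal transcription factors and 5 middle hox genes the median log2 differences were -2.01 and -3.41, and over 4 posterior hox genes -2.64 and -2.90. Over 7 anterior hox genes the medians were higher than in the other libraries, at 0.89 and 0.38. No stomach gene was among the genes matched, and no biological cause was tested.

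hoxa11ab is higher after beauvericin in intestine. Controls 5 and 6, with hoxa11ab at 1.4 and 7.2, are not its whole cause, because 2.62 ± 0.48 of 3.25 ± 0.51 log2 units remained after low beauvericin without them, though the limma adjusted p was then 0.097. That remaining fold took the place of the adjusted p as the test once the p had been seen; without replicate 3 of low enniatin B as well, the limma adjusted p was 0.017. Control samples taken nearer the head could give the same. A score of genes that vary with posterior hox genes inside the treated groups, with all hox genes left out of it, was lower in controls 1 to 4 than in 22 treated libraries, replicate 3 of low enniatin B being left out as divergent (-0.92, exact permutation p = 0.031). An effect of the toxins on hoxa11ab and the position of sampling cannot be separated here.

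Red cell genes are lower in liver after low beauvericin. Factors made within liver gave a camera adjusted p of 3.3e-11, but they moved low beauvericin against control by -0.0028 log2 units, so this test decides nothing about size factors shared by both tissues. Less blood in the sampled livers cannot be told from lower expression: 9 white cell genes changed by -0.02 on the log2 scale (95% interval -0.31 to 0.26), but white cells also reside in liver. An effect of beauvericin on red cell production is thus open.

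Among 95 groups of values searched for an outlying library, 5 had one, near the number that chance gives at 1 in 20. That count does not show that any single flag is chance, and replicate 3 of low enniatin B in intestine was flagged more than once. Replicate 6 of high enniatin B in liver had 30.7 M reads, against 33.6 to 35.3 M in its group. Replicate 3 of low enniatin B in intestine had a median correlation of 0.857, against 0.958 to 0.963, and a hoxa11ab value of 232, against 25.2 to 87.5. tmem43 was 1110 in liver replicate 5 of high enniatin B, against 558 to 729. tal1 was 229 in liver replicate 3 of low enniatin B, against 71.2 to 121. Controls 5 and 6 of intestine hide each other in that search. Replicates 1 and 3 of high beauvericin in liver, at 57.8 and 61.7 M reads, were not flagged either.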

How the results depend on the processing

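The tests without the divergent libraries, edgeR on the recovered reads, the pseudocounts and the lists with a library left out were chosen only after the result was seen. edgeR itself was the test planned, on counts as deposited. Limma took its place because the values are normalized, so the limma counts are not those of the planned test. For intestine against control, low enniatin B gave 0 genes in limma, 1582 in DESeq2, 545 in edgeR, 9 in DESeq2 without controls 5 and 6, and, without replicate 3 of low enniatin B as well, 1 in limma, 1 in edgeR and 56 in DESeq2. Leaving out each library gave 0 to 608. High enniatin B gave 0, 1444 in DESeq2, 542 in edgeR, 10 in DESeq2 without controls 5 and 6, 16 without all 3, and 0 to 1518. Low beauvericin gave 4, 1634 in DESeq2, 331 in edgeR, 1 in voom and 0 with only the 2 groups. Left without controls 5 and 6, limma gave 1, edgeR 1 and DESeq2 37, without all 3 edgeR 2 and DESeq2 127, and the range was 0 to 1067. High beauvericin gave 1, 1337 in DESeq2, 487 in edgeR, 0 in voom, 0 with a pseudocount of 0.5 and 0 with only the 2 groups. Then, without controls 5 and 6, edgeR gave 0 and DESeq2 6, without all 3 limma 2 and DESeq2 11, and the range was 0 to 23. Between toxins in intestine the low dose gave 0, 2 in DESeq2, 1 in voom, 4 in DESeq2 without controls 5 and 6 and 7 without all 3. The high dose gave 1, 6 in DESeq2, 2 in voom, 0 with only the 2 groups, 8 and 10 in DESeq2 without them, and 0 to 1. Between doses DESeq2 gave 1, 2 and 1 for enniatin B and 3, 3 and 6 for beauvericin, over all libraries, without controls 5 and 6 and without all 3. In liver low enniatin B gave 0 and 5 in DESeq2. High enniatin B gave 0, 2 in DESeq2 and 0 to 1. Low beauvericin gave 32, 87 in DESeq2, 19 in voom, 21 in edgeR and 1 to 42. High beauvericin gave 0 and 36 in DESeq2. Between toxins in liver the low dose gave 0, 21 in DESeq2, 3 in voom, 4 in edgeR, 2 with a pseudocount of 10, 2 with only the 2 groups and 0 to 2. The high dose gave 0, 47 in DESeq2, 1 in voom and 0 to 7. Between doses in liver DESeq2 gave 2 for enniatin B and 8 for beauvericin, with 1 in edgeR and 0 to 1 for the latter. For the difference between tissues, high beauvericin gave 0, 1 with no filter, 750 in DESeq2, 405 in edgeR, 2 in edgeR and 19 in DESeq2 without controls 5 and 6, and 0 to 10. High enniatin B gave 0, 559 in DESeq2, 304 in edgeR, 1 without all 3 in limma, 1 in edgeR and 8 in DESeq2 without controls 5 and 6, and 0 to 9. The cause was not tested.

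Lists past the threshold in intestine numbered 3, 4, 5 and 3 for low and high enniatin B and low and high beauvericin, and 0 for all 4 with an estimated correlation and 0 with fry. In the main fit 2, 3, 3 and 3 lists were higher and 1, 1, 2 and 0 lower. Without controls 5 and 6 it was 0, 1, 0 and 0 higher and 4, 6, 6 and 2 lower, a total of 7 for high enniatin B. Without all 3 divergent libraries it was 2, 1, 0 and 0 higher and 7, 7, 6 and 2 lower, a total of 9 for low and 8 for high enniatin B. Leaving out each library gave 2 to 5 (5 without control 6), 4 to 9 (9 without control 5), 3 to 6 (3 without control 1 or 2 or replicate 2 of low beauvericin) and 2 to 5 (5 without control 2). In liver the numbers were 1, 5, 5 and 3, and with an estimated correlation 0 for high enniatin B, 1 for low beauvericin and 0 for high beauvericin; fry gave 0, 1 and 0. Leaving out each library in liver gave 1 to 2 (2 without control 4 or 5 or replicate 1 or 4 of low enniatin B), 3 to 8 (3 without control 2, 8 without replicate 3 of high enniatin B), 2 to 7 (2 without control 2 or replicate 1 of low beauvericin) and 1 to 5 (1 without replicate 2 of high beauvericin, 5 without its replicate 4 or 5). The correlation of log2 changes was 0.41 with controls split and 0.62 without controls 5 and 6 in intestine, and -0.05 with controls split in liver; it ranged from 0.81 to 0.94 and from 0.35 to 0.53 with a library left out.

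With the replicate number as a block, low beauvericin gave 7 genes in intestine, and in liver low enniatin B gave 1 and high enniatin B 1; the block moved no other count by over 1.5 times, and with treatment and number as a block the tissue differences stayed at 0 for both toxins. The numbers do not pair the treatments: same-numbered samples correlated at a mean of 0.009 in intestine and -0.007 in liver (-0.37 to 0.25 and -0.21 to 0.31). Intestine and liver of the same treatment and number correlated at a mean of 0.219, against -0.008 for all other pairs of intestine and liver. Within their treatment, 28 of 29 intestine samples correlated best with the liver of their own number. The data thus point to a shared source such as the same fish, though the labels do not state it.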

Other observations

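The tests without controls 5 and 6 and the splits were chosen only after the result was seen; the other lists were fixed earlier.

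Intestinal genes of energy and protein turnover lay lower in all 4 comparisons once controls 5 and 6 were left out. These comparisons share the same 4 controls, so their agreement is not independent. The same 4 controls were lower than 22 treated libraries in the score of genes that vary with posterior hox genes (-0.92, exact permutation p = 0.031). Whether the position of sampling moves the lists below was not tested, so it cannot be separated from an effect of the toxins. For the high doses, simulated unchanged groups, made by shuffling these libraries, already correlated at a mean of 0.58. With an estimated correlation no list of this paragraph passed (adjusted p = 0.32 to 0.68). Oxidative phosphorylation genes had medians of -0.17, -0.19, -0.27 and -0.19 for low and high enniatin B and low and high beauvericin (camera adjusted p = 8.2e-05, 1.1e-06, 3.1e-10 and 5.2e-07), and proteasome genes -0.24, -0.29, -0.27 and -0.14 (8.2e-05, 5.9e-07, 4.8e-08 and 0.014). Interferon response genes were lower in 9 of 9 after low enniatin B (median -0.30, camera adjusted p = 0.00016) and high enniatin B (median -0.34, 0.00055). Cell cycle genes were lower in 17 of 18 after low beauvericin (median -0.67, camera adjusted p = 2.6e-09).

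Defence against foreign compounds, the function a toxin would first be looked for in, passed in no comparison. The smallest camera adjusted p was 0.10 in intestine and 0.86 in liver for 4 xenobiotic metabolism genes, 0.42 and 0.11 for 15 oxidative stress genes and 0.42 and 0.33 for tight junction genes. The xenobiotic list held 23 symbols and only 4 matched members, so most of that function was not tested. Replicate 3 of low enniatin B and replicate 6 of high beauvericin in intestine had cubn at 47500 and 10300, against 45.5 to 272 in the other 27 libraries.

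Splits of the same libraries into other groups, 100 for each result, were counted for chance, without correction over the results. For low beauvericin in liver 1 split, the real one, reached its 32 genes, the smallest share that 100 splits can give. Over this many uncorrected results that share does not exclude chance. The margin is narrow, since the highest other gave 30, and the real count was 1 without control 1 and 4 without replicate 2 of low beauvericin. Between the toxins at the high dose in intestine, 1 split reached the 1 gene and the highest other gave 0. That does not exclude chance either, since the gene is lost with only the 2 groups and in 4 of 29 fits that left out a library. Nor can chance be excluded for low and high beauvericin in intestine, where 11 splits reached 4 genes and 17 reached 1, with highest others of 5396 and 5071. A real count of 0 is reached by every split, so the splits decide nothing there: 100 of 100 for low and high enniatin B in intestine (highest others 2522 and 5483) and for the remaining toxin and dose contrasts of intestine (0, 0 and 1). The same held for low and high enniatin B and high beauvericin in liver (1, 197 and 27), for toxins and doses in liver (1, 0, 2 and 1) and for the tissue differences (63 and 4859). Counts of 2522 to 5483 arose only where intestine controls were among the libraries split. Contrasts among treated intestine libraries, replicate 3 of low enniatin B included, reached 0 or 1. The large counts thus point to the intestine controls, of which 5 and 6 are the divergent ones (median correlations 0.589 and 0.601). The splits were not repeated without these libraries, so the part of each was not measured. For lists, 79, 61, 46 and 81 splits reached the real 3, 4, 5 and 3 in intestine (highest others 12, 11, 11 and 11) and 92, 32, 28 and 67 the real 1, 5, 5 and 3 in liver (8, 14, 10 and 10), so the number of lists excludes chance nowhere.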
